A study of Mus musculus with 13 samples.

How the data were processed

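PolyA RNA from mouse tongue epithelium was sequenced from 13 samples, per the labels. In 6 of them a Krt14-Cre transgene was present together with a Cre-inducible H3K36M histone, a lysine-to-methionine mutant of histone H3 that blocks methylation of lysine 36, and 7 carried the inducible allele without Cre and served as the control group. Libraries were made with a directional poly(A) kit and read as single ends, per the labels' protocols. STAR and DESeq2 are named in the submitters' processing notes without versions, together with the mouse build GRCm38 (mm10). The gene annotation and the read-counting tool were not given in the sources used here.

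The files held 1 table of the authors' DESeq2 statistics for H3K36M against control and 2 tables of gene ontology (GO) terms, with no values of single samples. Per the file headers, the mean and the control and comparison levels were normalised counts, a signal scale made by the authors. The log2 fold change and its standard error, on the log2 scale, and the Wald statistic, a score, were deposited by the authors. The p-values and adjusted p-values were the authors' as well, and the authors' deposited GO tables gave a fold enrichment, which is a ratio, with its p-value and false discovery rate from a Fisher test. In all 19909 genes with reads, 13 times the mean equalled 7 times the control level plus 6 times the comparison level within a relative tolerance of 1e-06, and the sign of the fold change followed the order of those levels, so positive values mean higher in H3K36M. The levels are therefore fitted group values, and no spread between samples can be computed from them.

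No count test could be fitted without values of single samples. The main result, fixed before the data were examined, was the authors' adjusted p below 0.05 with the sign of their log2 fold change. Of 24972 genes, 17449 had an adjusted p. The authors' table gave none to 7348 genes of low mean, 2285 of them with reads, or to 175 genes marked as outliers, which are called set aside here. The smallest mean with an adjusted p was 0.405 normalised counts. In 26 rows the gene name had been turned into a calendar date. They stayed in the counts, where 1 was past the threshold, and none is named. The 95% intervals were computed from the authors' standard errors. The p-values rest on 7 and 6 samples that the labels do not tie to named animals, so they measure the spread between these samples.

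Gene lists (39) were fixed before the data were examined. They were tested with limma 3.58.1 in R 4.3.3 (cameraPR, inter-gene correlation 0.01) on the fold change divided by its standard error, two-sided, for lists of at least 5 members, with Benjamini-Hochberg adjustment over lists. An estimated correlation needs values of single samples and was not available. The preset value treats list members as nearly independent, so a set p does not measure how far they vary together between samples. Set-aside genes and genes of low mean entered these tests. In the alternative with signed −log10 p as the statistic, the set-aside genes dropped out, as they have no p. Named genes were, among those past the threshold with a mean of at least 50 normalised counts and without clone or predicted names, the 10 largest increases and 10 largest decreases, then from each list the 4 members with the smallest adjusted p past the threshold or, where none passed, the 2 with the highest mean, and always H3f3a, H3f3b, Krt14, Setd2, Nsd1, Nsd2 and the sex-linked list. Genes named outside this rule are said to be. Of the genes the rule selects, 1 is not reported here. Positions are from GENCODE M21 on GRCm38, where 97.8% of the table's symbols occurred once.

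Depth was known only in part. A gene read in 1 library alone has a summed normalised count that is a whole multiple of the value of 1 read there, and 13 such values were recovered. For each value, the genes read once all had their fitted excess in the same group, which gave 7 control and 6 H3K36M libraries. Whole multiples were accepted within a relative tolerance of 1e-09 and up to 500 reads. The relative depths (size factors) ran from 0.728 to 1.23 in control and from 0.645 to 1.77 in H3K36M, and the mean total was 15749830 normalised counts per library, date-named rows left out. These libraries carry letters here and were not matched to any labelled sample. Of 1282 genes with a summed normalised count under 2.2, 968 were whole multiples of 1 value. Genes read in several libraries mostly did not resolve into whole reads, as would also be seen if the authors had used normalisation factors for single genes, which no source used here states. Counts per library were therefore not reconstructed, and the size factors and the shares of single libraries hold only if 1 factor per library applies. Read numbers for a group are approximate, the product of a fitted level and the summed size factors. Where a group held 0 reads, the fold is a bound against a floor of 3 counts over that group, and where it held 1 to 3, an exact 95% interval is given. Both cover counting error only. A between-library coefficient of variation (CV) was derived from each standard error, as the negative binomial dispersion that gives it at the fitted levels.

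Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data with the real standard errors of the 17449 genes, 200 genes with a mean of at least 50 normalised counts were changed. Of the 50 changed at each size, 32% were called at a log2 fold change of 1, 80% at 2, 96% at 3 and 94% at 4, with 4 false calls among 155. For the set test, with statistics drawn independently for each gene, both shifted lists and none of the other 36 were called. All 13 simulated size factors were recovered, and the 703 genes assigned to a single library all had the right library and number of reads. That simulation used 1 factor per library, so it does not test the recovery under normalisation factors for single genes. Alternatives covered the threshold, a minimum fold, a filter on the mean, the p adjustment, a test against a log2 change of 0.5, removal of marker genes of other cell types, and the settings of the set test. Other tests, other normalisations, pseudocounts and leaving out samples need values of single samples and were not run.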

Results

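Bulk polyA RNA sequencing compared tongue epithelium of mice, 6 samples carrying Krt14-Cre and the inducible H3K36M histone and 7 Cre-negative control samples. Krt14-Cre is active in the basal layer of stratified epithelia. The title of the study names loss of H3K36 methylation, cell plasticity, gland formation and squamous carcinogenesis, and the comparison asks which transcripts differ when the mutant histone is expressed. Every H3K36M sample was Cre-positive and every control sample Cre-negative. Effects of Cre itself therefore cannot be told apart from those of the mutant histone.

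Glandular and simple-epithelial transcripts were higher in H3K36M, and the hard keratins of the filiform papillae, the horny projections of the tongue surface, were lower. In the authors' deposited table, 322 genes were higher and 277 lower at an adjusted p below 0.05 among 17449 tested (DESeq2 by the authors), and 1714 had an unadjusted p below 0.05. Of the 599 genes past the adjusted threshold, 284 were higher and 216 lower by more than 1 on the log2 scale. With the statistic centred and scaled, an alternative chosen after the data were seen, 374 were higher and 418 lower. The median fold was 5.77 among the higher genes and 3.12 among the lower ones. The median log2 fold change of all tested genes was 0.07. A further 175 genes were set aside as outliers by the authors' tool, 151 of them with a higher and 24 with a lower level in H3K36M, and they enter none of these counts.

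The 10 largest increases included Tff2, Muc19, Pigr and Sprr2d. Tff2, a mucosal trefoil factor on chromosome 17 (31141049 to 31144282, GRCm38), went from a fitted level of 5.80 to 6933 normalised counts in the authors' deposited table, a log2 fold change of 10.22 with a standard error (SE) of 1.93 and adjusted p = 1.76e-05. Muc19, a gel-forming salivary mucin, rose by 8.12 (95% interval 5.17 to 11.06), Pigr, the receptor that carries IgA across epithelia, by 7.01 (SE 1.40), and Gp2 by 6.66 (SE 1.57) in the authors' deposited table. Ccl28, a mucosal chemokine, rose by 6.37, Bpifb2 by 6.24 and the water channel Aqp5 by 6.21 on the same scale of that deposited table, each with an SE between 1.26 and 1.58. Sprr2d, a cornified envelope protein, rose by 6.89 (SE 0.81) in the authors' deposited table. The secretoglobins Scgb2b17 and Scgb2b15 are near-identical copies that can share reads. From the levels in the authors' deposited table, each had about 1 read in control, against about 1935 and 1915 in H3K36M, ratios of 2163 (counting interval 388 to 85497) and 2141 (384 to 84614). With the spread between libraries, the 95% intervals of their log2 fold changes ran from 6.54 to 15.86 and from 6.53 to 15.85 (SE 2.38 each). Muc19 had a fitted control level of only 0.576 normalised counts. The between-library CV implied by the SE was 0.984 for Sprr2d and 1.49 (Ccl28) to 2.39 (Tff2) for the others of these 10. Among the 10 largest decreases it ran from 0.492 (Spink6) to 1.04 (Krtap4-13). Whether the largest increases were shared by the H3K36M libraries or carried by few cannot be told without values of single libraries.

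The 10 largest decreases included Gprc5d, 4 keratin-associated genes and Btc. Gprc5d, a receptor of keratinising cells, had about 3 reads in H3K36M and 746 in control by the levels of the authors' deposited table, a ratio of 222 (counting interval 75.8 to 1081). In the authors' deposited table, the keratin-associated genes Krtap4-13, Krtap4-9, Krtap4-16 and Krtap4-8, whose close copies can share reads, had log2 fold changes of −4.70 (SE 0.84), −3.70 (SE 0.82), −3.32 (SE 0.66) and −3.23 (SE 0.68). Btc, an EGFR ligand on chromosome 5 (91357261 to 91402994), fell by 3.69 (SE 0.42, adjusted p = 4.76e-15), the protease inhibitor Spink6 by 3.34 (SE 0.42), the netrin receptor Unc5c by 3.37 (SE 0.71), Klk15 by 3.23 (SE 0.50) and Cryba4 by 3.07 (SE 0.61) in the authors' deposited table.

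**Figure D1:**
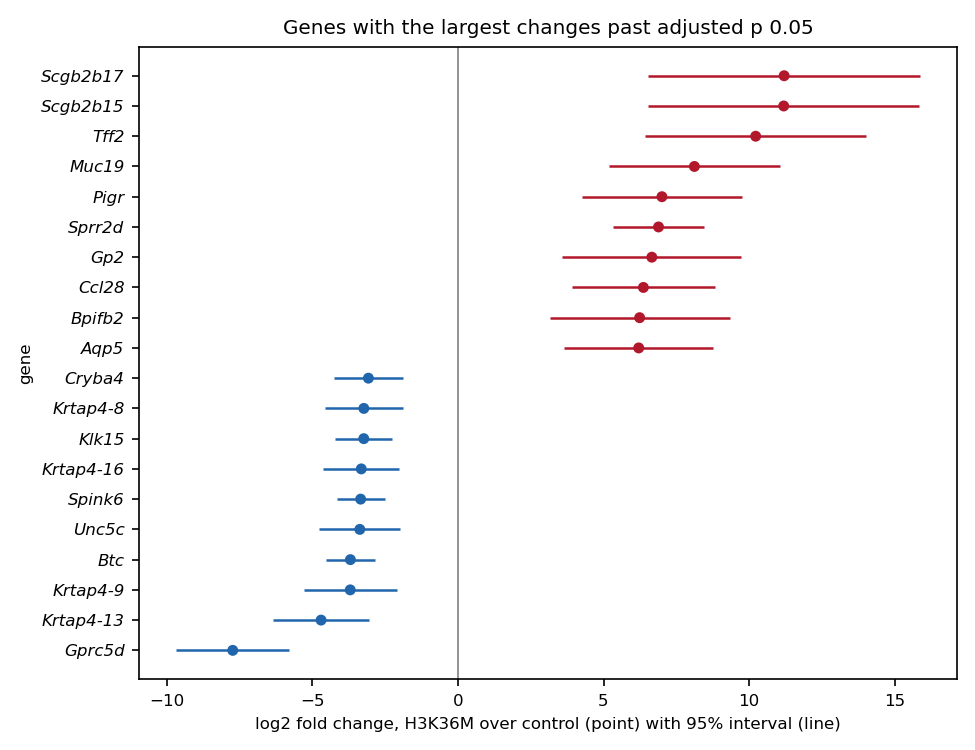
Log2 fold changes of H3K36M over control (horizontal axis) from the authors' deposited table for the 10 largest increases and 10 largest decreases, with 95% intervals as lines and one gene per row. The interval is wide for Tff2 (6.43 to 14.01) and narrower for Btc (−4.52 to −2.86).

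Of 22 tested members of the list of filiform papilla and hard keratin genes, 12 were lower and 0 higher in the authors' deposited table (17 lower when adjusted over the list alone), with a median log2 fold change of −1.61. The list was lower as a set (limma cameraPR, adjusted p = 4.72e-21). Krt36 on chromosome 11 (100102007 to 100105626), a keratin of the filiform papillae, fell by 1.65 (SE 0.31), Krtap13 by 1.99 (SE 0.45), Krtap3-1 by 1.96 (SE 0.44) and Krtap3-3 by 1.89 (SE 0.45) in the authors' deposited table. Skeletal muscle markers had a median log2 fold change of −1.75 in the same comparison.

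Simple and ductal epithelium genes moved the other way. Of 21 tested members, 8 were higher and 0 lower in the authors' deposited table (8 and 0 adjusted over the list alone), and 2 more were set aside. The set test gave adjusted p = 4.29e-13. Krt19 on chromosome 11 (100140810 to 100148665), a keratin of ducts, rose by 3.47 (SE 0.39), Krt7 by 2.71 (SE 0.48), Muc1 by 3.81 (SE 0.79) and, as above, Pigr by 7.01 in the authors' deposited table. Krt8 and Krt18, keratins of simple epithelia named after their values were seen, rose by 3.13 (SE 0.71) and 2.22 (SE 0.67) there.

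Salivary secretory genes were higher as a set (cameraPR adjusted p = 1.27e-16). Of 20 tested members, 8 were higher and 0 lower in the authors' deposited table (10 and 1 adjusted over the list alone), and 9 others were set aside, all 9 with a higher level in H3K36M. Among all 175 genes set aside, 151 were higher, so this direction is no added evidence for the list. The median log2 fold change of the tested members was 2.78, also with Smgc at its bound. Bpifa1 rose by 2.74 (SE 0.50) in the authors' deposited table. For Smgc, no control read was apparent and about 227 reads lay in H3K36M, at least 84.6-fold higher against a floor of 3 counts over the control group. It overlaps Muc19 at the same locus, so the reads of the pair cannot be fully separated. Some secreted genes drew their reads from few libraries. The same H3K36M library gave 91.5% of the normalised count of Scgb1b3 and 80.2% of that of Scgb1b20, both named after their values were seen, and it alone held the reads of the cartilage genes Clec3a and Col10a1.

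Stratified keratinocyte genes changed in both directions. Among suprabasal and cornified genes 4 of 58 tested were higher and 4 lower in the authors' deposited table (5 and 6 adjusted over the list alone), and the set was not past the threshold (adjusted p = 0.584). Krt1, a keratin of epidermis, rose by 4.44 (SE 0.64) and Sprr2e by 6.62 (SE 0.96), whereas Krt76, a keratin of oral epithelium, fell by 1.93 (SE 0.31) and Krt24 by 1.37 (SE 0.26) in the authors' deposited table. In the stress and wound list 3 of 21 were higher (S100a8 by 3.85, S100a9 by 4.08, Sprr2d) and 1 lower (Serpinb3c, log2 fold change −2.81) in the authors' deposited table (4 and 2 adjusted over the list alone, set adjusted p = 0.502, but 0.0462 with signed −log10 p as the statistic). S100a8 and S100a9 are also members of the neutrophil list, which was higher as a set (adjusted p = 3.47e-06, median log2 fold change 2.10). Of 20 basal genes 1 was lower and 0 higher in that deposited table (1 and 0 adjusted over the list alone, set adjusted p = 0.589), namely Krt14, the gene whose promoter drives Cre, by 0.87 (SE 0.26, adjusted p = 0.0292). The sebaceous list had 2 higher of 25, Krt79 by 1.39 (SE 0.24) and Cidea by 0.93 (SE 0.28), and 0 lower in the authors' deposited table, the same counts when adjusted over the list alone (set adjusted p = 0.215, but 0.0179 at a mean of at least 50).

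**Figure D2:**
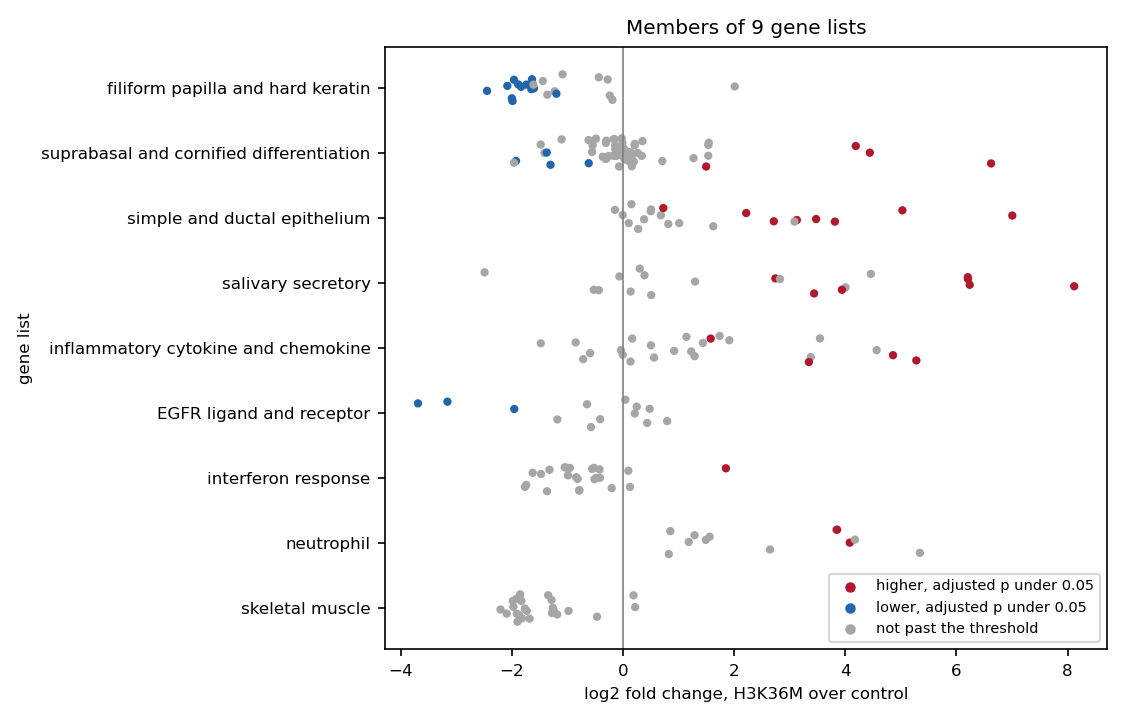
Log2 fold changes of H3K36M over control (horizontal axis) of tested members of 9 gene lists (rows) from the authors' deposited table, coloured by whether they passed adjusted p 0.05. Smgc lies outside the axis and is not drawn. All 12 coloured hard keratin genes lie below 0 and all 8 coloured simple epithelium genes above it.

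Among signalling lists, that of EGFR ligands and receptors, which also holds other genes of the ERBB family, had 3 lower and 0 higher of 13 in the authors' deposited table (4 and 1 adjusted over the list alone, set adjusted p = 0.00035, but 0.347 with a rank-based test). These were Btc, Nrg1, with a log2 fold change of −1.96 (SE 0.38), and the receptor gene Erbb4, with −3.16 (SE 0.75), in that deposited table. Inflammatory cytokines and chemokines had 4 higher and 0 lower of 24 in the authors' deposited table (6 and 0 adjusted over the list alone, set adjusted p = 1.96e-05): Il23a by 4.86 (SE 0.89), Cxcl5 by 5.28 (SE 1.42), Lcn2 by 3.34 (SE 0.82) and Cxcl14 by 1.58 (SE 0.50). Neutrophil markers were higher in the same comparison (set adjusted p = 3.47e-06), with a median log2 fold change of 2.10 over 12 tested genes in the authors' deposited table. The interferon list was lower as a set over 31 members (cameraPR adjusted p = 1.46e-05). Of these, 7 were set aside, all with a lower level in the authors' deposited table. With signed −log10 p as the statistic these 7 drop out, and the other 24 gave a set adjusted p of 0.271. Statistic and members changed together there, so the loss cannot be put down to either. The only called gene of the list, Oasl1, was higher by 1.85 (SE 0.51) in the authors' deposited table. The list of WNT targets also holds genes of WNT ligands. It had 2 lower of 22, Bambi (log2 fold change −2.07, SE 0.31) and the ligand gene Wnt5a (−0.88, SE 0.25), in the authors' deposited table. The hedgehog list had 1 lower of 13, Gli3 (−0.96, SE 0.24), there. Neither list passed as a set (adjusted p = 0.371 and 0.435), but the WNT list did at a mean of at least 50 (0.0398). Of the YAP and TAZ list 1 of 20 was higher (Myof, 0.59) and 1 lower (F3, −1.70) in that deposited table, with set adjusted p = 0.529. In these 3 lists and the interferon list the counts were the same when adjusted over the list alone. Immediate early and heat shock genes were higher as a set (adjusted p = 0.00989), with 1 called gene of 21 in the authors' deposited table, Egr3 by 2.06 (SE 0.48), but the set call was lost in 3 of the 6 alternatives.

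No list member passed in the lists for proliferation (35 tested), NOTCH (15), taste bud (18), p53 (20), invasion and matrix (24), H3K36 machinery (24), PRC1 and PRC2 (26) and HOX (12) in the authors' deposited table, by the authors' DESeq2. At an unadjusted p below 0.05 these held 0, 1, 1, 0, 3, 2, 1 and 2 genes, and adjusted over the list alone 1 invasion gene was higher and 1 HOX gene each was higher and lower. As sets they had adjusted p from 0.0643 (HOX) to 0.827 (H3K36 machinery). But the HOX list passed at a correlation of 0 (adjusted p = 0.026), with the rank-based test (0.00473) and with log2 fold change as the statistic (1.28e-12). It did not at a correlation of 0.05 (0.276) or with signed −log10 p (0.665), where its set-aside members drop out. The proliferation list passed with the rank-based test (0.030). Mki67 had a log2 fold change of 0.19 (SE 0.42) and Pcna −0.04 (SE 0.30) in the authors' deposited table. Of the p53 list, Perp stood at −0.29 (SE 0.23) and Cdkn1a at 0.05 (SE 0.44), of the NOTCH list Jag1 at −0.30 (SE 0.15) and Notch2 at 0.23 (SE 0.41), and of the taste bud list Itpr3 at 0.32 (SE 0.95) and Pou2f3 at 0.52 (SE 0.20) in the authors' deposited table. Vim (−0.44, SE 0.69) and Mmp2 (0.64, SE 0.24) of the invasion and matrix list, Morf4l1 (−0.18, SE 0.16) of the H3K36 machinery, Aebp2 (0.16, SE 0.17) and Rbbp7 (0.08, SE 0.24) of the PRC1 and PRC2 list, and Hoxc13 (−1.36, SE 0.51) and Hoxd8 (−0.06, SE 1.25) were likewise not past the threshold in the authors' deposited table. The HOX list had 8 further members set aside, all higher in H3K36M, as were 151 of all 175 genes set aside. The germline list had Piwil2, a PIWI protein of the germline, higher by 2.80 (SE 0.47) as its 1 call of 17 in the authors' deposited table, and the histone H3 list Hist1h3d, a gene with near-identical copies, by 3.59 (SE 0.57), 1 of 11 (1 and 2 adjusted over the list alone, set adjusted p = 0.191 and 0.0684, the latter 0.0476 at a correlation of 0). In the authors' deposited table H3f3a (−0.01, SE 0.36), H3f3b (0.19, SE 0.21), Setd2 (−0.02, SE 0.28), Nsd1 (0.11, SE 0.24) and Nsd2 (0.40, SE 0.20) did not pass. Levels of whole genes, those of the histone H3 list among them, give no measure of the mutant histone itself. No mitochondrial transcript of that list had reads in the table.

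Markers of other cell types moved too. Skeletal muscle genes were lower as a set (adjusted p = 3.66e-06), with a median log2 fold change of −1.75 over 24 genes and 0 past the threshold, 1 at unadjusted p below 0.05, in the authors' deposited table. Myh4 stood at −2.10 (95% interval −4.44 to 0.25) and Tnnt3 at −1.98 (SE 1.07) there. At a correlation of 0.05 the muscle set had adjusted p = 0.00106 (cameraPR). How far these genes vary together between samples could not be estimated, so the set p can overstate the evidence. The neutrophil list was higher as a set (adjusted p = 3.47e-06), with S100a8 and S100a9, which keratinocytes also express, as its 2 called members of 12 in the authors' deposited table and 6 when adjusted over the list alone. Dct, a melanocyte gene, fell by 1.80 (SE 0.43) as the only call of 7 in the authors' deposited table, also when adjusted over the list alone (set adjusted p = 0.237). Fibroblast (Dcn −0.20, SE 0.31, Gsn 0.05, SE 0.76), smooth muscle (Acta2 −0.17, SE 0.52, Rgs5 −1.12, SE 0.94), endothelial (Pecam1 −0.50, SE 0.90, Vwf 1.09, SE 0.96), T cell (Thy1 0.32, SE 0.57, Cd247 −0.62, SE 0.44), macrophage (Cd68 0.18, SE 0.25), dendritic (Cd74 −0.13, SE 0.57, H2-Aa −0.52, SE 0.23), B and plasma cell, mast cell (Cma1 −0.45, SE 1.06, Mcpt4 −0.61, SE 1.10), nerve (Mbp −0.08, SE 0.57, Pmp22 −0.53, SE 0.52) and adipocyte (Fabp4 0.20, SE 0.72, Plin4 0.00, SE 1.18) genes had no call in the authors' deposited table, also when adjusted over the list alone, and set adjusted p from 0.0643 to 0.827. Of 10 adipocyte genes with reads 5 were set aside, all 5 with a higher level in H3K36M in the authors' deposited table. So were 151 of all 175 genes set aside. The adipocyte set adjusted p of 0.0643 became 0.0476 at a correlation of 0 and 4.5e-10 with log2 fold change as the statistic. It was 0.157 at a correlation of 0.05. With signed −log10 p the set-aside genes drop out, and the 5 left showed no shift as a set (set adjusted p = 0.987). Of the 4 adipocyte genes tested, 3 were above 0 and 1 below, with a median log2 fold change of 0.10. The macrophage gene Lyz2 (log2 fold change 3.33, SE 1.18) and the plasma cell gene Jchain (3.10, SE 1.37) were set aside in the authors' deposited table. Sex-linked genes varied strongly between libraries, with Xist at 0.19 (SE 1.37), Ddx3y at 0.32 (SE 2.44), Eif2s3y at 0.21 (SE 2.89), Kdm5d at 0.42 (SE 2.89) and Uty at 0.33 (SE 2.89) there and no call of 5 (set adjusted p = 0.962).

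The authors' deposited GO tables listed 10 terms for the higher and 12 for the lower genes, without gene names. These 2 deposited tables of the authors drew on different term sets and on gene lists of different size, with 1828 genes in tissue development in the table of higher genes and 207 in that of lower genes, so their folds are not on the same basis. Both titles give a log2 fold change above 1, with no sign stated for the lower genes. Terms of the higher genes included keratinization with 8 genes and an enrichment of 11.78-fold (FDR 0.0072), and positive regulation of cholesterol metabolic process with 6 genes and 23.7-fold (FDR 0.00979). Terms of the lower genes in the authors' deposited table included intermediate filament organization with 12 genes and 20.19-fold (FDR 1.05e-08).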

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

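All tests in this part were chosen after the results were seen. Of 6 H3K36M libraries, 1 (library B) alone held every read of the cartilage genes Clec3a (175 reads) and Col10a1 (113), of Hoxb3 (52), Hoxa2 (35) and Hoxa7 (22), and of the cilia genes Foxj1 (20) and Dnah5 (12). Another, library C, alone held the 80 reads of the salivary gene Mucl2. Each was picked out because 1 library stood apart from the other 5, at 0. Genes with 20 or more reads in 1 library alone numbered 16, and all 16 were set aside by the authors' tool. Chance picks out about 1 in 20 groups by this rule, but a gene read in 1 library alone meets it by construction.

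In the genes set aside, 151 were higher in H3K36M against 24 lower, a signal outside the counts of the report. Acan, a cartilage gene, stood at a log2 fold change of 10.28 (95% interval 4.41 to 16.15), and the salivary genes Muc5b at 9.43 (SE 1.80) and Dmbt1 at 6.36 (SE 2.25) in the authors' deposited table. Replacement of outlying control counts before deposit is argued against, since 3 set-aside genes drew their reads from 1 control library alone. Of 15 set-aside genes read in 1 H3K36M library alone, 10 came from library B, which held 22.7% of the depth of that group. Library B alone held the reads of Clec3a, Col10a1, Foxj1 and Dnah5, as given above. Whether an unlike tissue composition of library B accounts for the other set-aside genes is not decided. Without the genes that prompted the question, and with each gene family counted once, 5 genes were left, 1 of them from library B (exact binomial p = 0.724, one-sided). These are too few to decide, and the test left out the very genes that set library B apart. Dissection, 1 library and a change in the tissue all stay open.

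The rise of simple-epithelial and salivary genes was weighed against a rise carried by 1 H3K36M library, with list members of a log2 fold change of at least 1 and a mean of at least 10. Of these, 1 of 8 simple and ductal genes and 7 of 18 salivary genes were set aside, and their median implied CV was 0.849 and 1.79. Several references were tried, with p from 2e-05 (the smallest that 100000 resamples can give) to 0.777, and none was suited. The 14 genes traced to 1 H3K36M library alone with 20 or more reads, all set aside, had means of at most 9.29, below those of the list members, and the set-aside genes and the cartilage genes, of which 15 of 18 were set aside, have a high CV built in. The 2 lists did differ in spread. Among simple and ductal genes, 6 of 8 had a CV below that of every raised set-aside gene outside the list. Among salivary genes, 2 of 18 did. Because a high CV is built into that reference, the difference gives no verdict for either list as a whole. For both lists a rise carried by 1 library therefore cannot be told apart from one shared by several without values of single libraries.

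Lower genes were frequent at both ends of genomic span. Among 10850 protein-coding genes with a mean of at least 50 normalised counts, 5 classes of 2169 to 2171 genes, from the shortest to the longest span, held 60, 14, 21, 21 and 72 lower and 47, 20, 23, 19 and 23 higher genes. The median span of the 188 lower genes was 32404 bp against 24928 bp for all genes, above 99.8% of 10000 random sets matched on mean expression, which argues against mean expression. Without keratin and keratin-associated genes, 158 lower genes had a median span of 57944 bp. Matched random sets drawn without both families had medians of at most 40414 bp. Loss of long mRNAs is argued against too: across genes, which are not independent replicates, the statistic rose with exonic length given span (partial rank correlation 0.115, bootstrap interval 0.0983 to 0.134), while its rank correlation with span was −0.024 alone and −0.095 given exonic length. An effect of H3K36M on long gene bodies, where H3K36 methylation lies, is a hypothesis the files do not test, and cells other than keratinocytes stay open.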

How the results depend on the processing

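The alternatives called statistic centred and scaled, CV under 1, and removal of airway, cartilage, salivary and secretoglobin genes were chosen after the data were seen. The reported 322 higher and 277 lower genes became 229 and 179 at adjusted p below 0.01, 118 and 79 with Bonferroni adjustment, 147 and 81 when a log2 change above 0.5 was tested, and 374 and 418 with the statistic centred and scaled, since its median was 0.159 and its scale 0.919. All other settings stayed within 1.5 times: 264 to 403 higher and 216 to 344 lower genes. Without airway, cartilage, salivary and secretoglobin genes 304 and 276 were called. Of 9 lists past the threshold, 5 passed in all 6 alternatives and the neutrophil list in the 5 it could be run in. The exceptions were the EGFR list (0.347 rank-based), the interferon list (0.271 with signed −log10 p, which also leaves out its 7 set-aside members) and the immediate early list (0.0777 at correlation 0.05, 0.424 with log2 fold change, 0.202 with signed −log10 p), and the cause was not tested. A further 7 lists passed in at least 1 alternative, among them HOX genes. No paired analysis was possible because the labels give no shared replicate numbers and the table holds no samples. Leaving out samples, other tests, other normalisations, pseudocounts, an estimated correlation, counts without library B and other splits of the samples were not run for the same reason, so chance in the grouping of samples was not tested. In the simulation with the real standard errors, a log2 change of 1 was called in 32% of the genes so changed, all with a mean of at least 50. Above that mean the median SE was 0.343, against 0.471 over all tested genes. What depth contributes to the share called was not tested.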

Other observations

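These gene groups were put together after the values were seen, from called genes among others, so their counts are no independent evidence, and the permutation test of genes read in 1 library was also chosen after the data were seen. Of 23 tested genes of columnar and intestinal epithelium, 18 were higher and 0 lower in the authors' deposited table. Gucy2c, the intestinal receptor of guanylin, rose by 3.88 (SE 0.35), the intestinal antigen Gpa33 by 5.67 (SE 0.62), Tff1 by 7.70 (SE 1.51) and Itln1 by 3.85 (SE 0.94) there. Of 21 genes of the piRNA pathway and early germline, 9 were higher and 0 lower in the authors' deposited table, with Pnldc1 at 3.68 (SE 0.57), Tdrd12 at 4.84 (SE 0.89), L1td1 at 5.43 (SE 0.69) and Piwil4 at 3.44 (SE 0.79). The smallest adjusted p of the genes looked at belonged to Mt3, a metallothionein, which rose by 5.24 (SE 0.28, adjusted p = 1.38e-75) in that deposited table.

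By family, 20 of 32 tested keratin-associated genes were lower and 3 higher, 7 of 11 secretoglobins and 5 of 9 Sprr2 genes were higher and 0 lower in the authors' deposited table, and these families hold close copies that can share reads. Of 18 airway and ciliated genes 13 were tested, 5 of them higher and 1 lower, and 5 were set aside. Of 18 cartilage genes 15 were set aside.

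Genes read in 1 library alone numbered 139 ± 122 (SD, n = 6) per H3K36M library and 50.7 ± 20.5 (SD, n = 7) per control library (exact permutation p = 0.0711, two-sided, over 1716 splits), which is not past 0.05. The H3K36M values were 143, 195, 63, 45, 352 and 35.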
